A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

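RNA from 4 mutant strains of the fission yeast Schizosaccharomyces pombe was hybridised to 4 dual-colour Agilent tiling arrays, 1 array per genotype. The strains lacked hrp3, alp13, hrp3 together with alp13, or clr3. Per the labels, RNA of cells in logarithmic growth in rich medium at 30 °C was extracted with hot phenol, treated with DNase and amplified with a linear amplification kit, with the mutant in the red dye (Cy5) and the wild type in the green dye (Cy3) on every array. There was no dye swap and no replicate check, so the spread given with each value is the standard deviation (SD) over the probes of a gene, which is technical. The number of arrays limits the precision.

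The scanner files held spot means and local backgrounds as fluorescence intensity, per the file headers of Agilent Feature Extraction 9.5.1.1. The same files held processed intensity values, per the file headers with background subtracted, detrended and dye-normalised, and their log10 ratio of red over green. The deposited value table of the authors held a score per probe. Its unit and normalisation were not given in the sources used here, and for probes with signal in both channels it lay close to the log2 ratio of the scanner files (slopes of 0.973 to 0.997 and Pearson correlations of 0.973 to 0.991). The table also held values of up to 1025, exact zeros and blanks, with 43, 199 and 9 values above 10 in size on the hrp3, double-mutant and clr3 arrays even among probes well above background in both channels, so it served only as an alternative, with probes well above background in both channels and absolute values of at most 10.

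Spot means were background-corrected with the normexp method of limma 3.58.1 (offset 50) in R 4.3.3, with version 1.17.8 of data.table, and each array was normalised on its own with a loess curve. Control spots (1417 per array) and spots that the scanner software called non-uniform or population outliers had no weight in the curve, and those outlier spots were left out. Besides the control spots, each array held 43802 probes of 60 nt, spaced every 100 bp on each strand, before the outlier spots were left out. Signals of single channels came from Aquantile scaling between arrays after the loess step. Later steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

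The array covered only part of the genome, mainly chromosome II, and its coordinates belong to an older assembly than the gene table at hand. The sequence of the tiled blocks was therefore rebuilt from the overlapping probes, with 0 mismatching bases, and genes were placed in each block by tRNA motifs and open reading frames under 1 offset per block. In the 2 long blocks of chromosome II, 219 of 222 and 458 of 471 reading frames of at least 500 nt then lay inside a gene, and at the right end of chromosome II 5 of 8 did. Of 12 conserved peptides sought in the rebuilt sequence as a check, 9 were found, and all 13 hits fell in the gene that encodes the peptide. The blocks around inv1, around nmt1 and on chromosome I rest on 1 frame each, and gene ends may be off by small distances. All coordinates given are those of the array files. Of 893 wholly tiled protein-coding genes, 867 had a coding strand, taken from their reading frame or from the naming of the cosmid they lie on, and 26 had none and were left out. The 22 genes whose reading frame ran against the cosmid naming are among the 26 left out. The cosmid naming gave 245 of the strands, so for some genes sense and antisense may be swapped.

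A feature was the set of probes on the coding strand (sense) or the opposite strand (antisense) of a gene, and antisense probes that lay on the sense strand of another gene were left out. Its value was the median over at least 2 probes of log2 of mutant over wild type. A feature was called higher at a value of at least 1 (2-fold) when at least 50% of its probes were well above background in the mutant channel. It was called lower at -1 or below when at least 50% were well above background in the wild-type channel. With 1 array per group no test across genes was possible and no p-value is given, so higher and lower are threshold calls. Named genes followed a rule: the 3 deleted genes, the 8 highest and 6 lowest sense and the 8 highest antisense values per array among called genes with at least 3 probes that all moved the same way, up to 4 members of each gene list with the largest values in size, and the 5 genes farthest above and below the sum of the single mutants.

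The 25 gene lists were the deleted genes, strain markers, histones, Tf2 retrotransposons, wtf genes, telomere-linked helicases, pheromone and mating genes, meiosis, stress-induced genes, chaperones, iron uptake, phosphate, nitrogen starvation, ribosomal proteins, ribosome biogenesis, glycolysis, hexose and glucose-repressed genes, Clr6 complexes, heterochromatin, remodellers, Set2 and histone chaperones, MBF-regulated genes of G1 and S phase, mitosis and septation, flocculation, and RNA decay. A further 2 lists were set by position, the right end of chromosome II and the mating-type region. A list median was compared with 10000 random lists of the same size matched on signal in 10 bins, and its percentile describes the array only. Percentiles were given for the 6 lists with at least 5 measured members, and not where a typical member had over 25% of its probes saturated. The lists, the named-gene rule, the thresholds, the comparisons and most of the alternatives were chosen before the data were examined. The lists by position took their final borders from the tiled blocks, and the probes that recur on the array (2536) and the filter on both channels were added as alternatives afterwards.

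Signal over background stands for depth on these arrays. Wild-type and mutant probes well above background made up 68.7% and 74.7% on the hrp3 array, 71.9% and 74.9% on the alp13 array, 75.3% and 88.4% on the double-mutant array, and 65.6% and 61.4% on the clr3 array. The 4 arrays were scanned in 2 sessions with 2 Agilent protocols (GE2-v5_95_Feb07 and GE2_107_Sep09): the hrp3 and double-mutant arrays in one session, and the alp13 and clr3 arrays in the other, on a shared slide. Genotype and array cannot be separated, and no fit with session or slide as a term was possible with 1 array per genotype.

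Alternatives were no background subtraction, median centring in place of loess, a loess curve fitted on sense probes alone, the processed signals of Agilent, the authors' value table, the mean of the 4 wild-type channels as reference, no filter on dim probes, at least 3 probes per feature, means over probes, no recurring probes, and a filter on both channels. Correlations across genes were set beside values from 500 simulations in which 2 unchanged mutants shared a wild type, with equal noise assumed in every culture. The calling steps were tested on simulated data: of 100 genes raised 3-fold and 100 raised 6-fold per array, all were called, with at most 2 of 611 unchanged genes called. Introns, untranslated regions and non-coding RNA genes were not analysed here, because the gene table gave no exons and no strand.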

Results

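RNA levels on both DNA strands were measured in 4 mutant strains of fission yeast against wild-type RNA on the same array, with 1 array for each of the 4 genotypes. Hrp3 is a chromatin remodeller of the CHD family, Alp13 is a chromodomain subunit of a Clr6 histone deacetylase complex, and Clr3 is the histone deacetylase of the SHREC complex of heterochromatin. The series title names antisense transcripts in mutant strains as the subject, so the question for each mutant was which genes gained or lost RNA on either strand. On the main normalisation 840 genes were measured on the sense strand and 810 or 811 on the antisense strand. The genes hrp3, alp13 and clr3 lie outside the tiled part of the genome, so the deletions themselves could not be checked by the signal of the deleted gene. Gene names rest on placing the gene table on the sequence of the array, whose assembly is older. The hrp3, alp13 and double-mutant strains carried another ade6 allele than the wild type, per the labels. The wild-type channels correlated across genes at 0.986 to 0.996 (Pearson) on the sense strand and at 0.914 to 0.956 on the antisense strand, and genes are not independent replicates. The most variable wild-type sense signals were those of rpl2502, SPBC9B6.11C, nmt1, cox7 and bgs1.

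Cells without hrp3 gained antisense RNA over 44 genes and lost it over 3, while only 8 genes were higher and 5 lower on the sense strand. Among the called genes whose probes all moved the same way, the highest antisense values were those of sen34, a subunit of the tRNA splicing endonuclease, at 2.0 ± 0.89 (log2, SD over probes), SPBC19C2.10 at 1.90 ± 0.80 and ngl1 at 1.89 ± 0.60. The recombination factor gene sfr1 stood at 1.76 ± 0.64, the membrane receptor gene izh2 at 1.72 ± 1.18, the ribosome-biogenesis helicase gene dbp7 at 1.71 ± 0.55, the splicing factor gene prp1 at 1.68 ± 0.74 and SPBC12D12.05C at 1.66 ± 0.77. The probes of sen34 spanned 2835961 to 2836820 on chromosome II and those of prp1 2643811 to 2646470. None of the 44 genes was lower or higher on the sense strand, and their median sense value was -0.08. The 3 genes with lower antisense, mag2 at -1.38, SPBC23G7.10C at -1.24 and SPBC23G7.13C at -1.05, all lie in the mating-type region. The antisense median over all 810 genes was 0.06.

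In sense RNA of the hrp3 mutant, SPBPB2B2.16C near the right end of chromosome II (4499751 to 4501110) was 3.57-fold higher, at 1.84 ± 0.43. Its neighbours SPBCPT2R1.01C at 1.34 ± 0.31, SPBCPT2R1.04C at 1.34 ± 0.28, SPBCPT2R1.02 at 1.16 ± 0.26 and SPBPB2B2.14C at 1.14 ± 0.49 were higher too. Most probes of SPBCPT2R1.01C and SPBCPT2R1.04C recur elsewhere on the array, so their values describe the repeat family. The small heat shock protein gene hsp16 reached 1.36 ± 0.46 with 25% of its probes saturated, the transcription factor gene atf21 1.04 ± 0.21 and SPBC24C6.09C 1.04 ± 0.29. The steepest fall was in mat1-Mc, the M-type mating regulator expressed from the active cassette, at -6.36 ± 0.46, and in mat3-Mc, its silent copy, at -5.25 ± 1.27. In the mutant channel only 20% and 60% of their probes were well above background, so the size of these falls is uncertain, and over the alternatives they ran from -8.43 to -6.13 and from -6.99 to -4.04. All probes of this pair recur between the cassettes, so the source cassette of the RNA is open. SPBC23G7.10C in the same region was at -2.42 ± 0.36, the telomere-linked helicase gene tlh2 at -3.19, and the iron-siderophore transporter gene str1 at -1.63 ± 0.49. The gene tlh2 belongs to a family of near-identical subtelomeric helicases. Copies outside the tiled sequence may add to its signal, so its values on all arrays may describe the family. The number of genes with higher antisense was 67 with the loess curve fitted on sense probes, 98 with Agilent's processed signals and 84 with the authors' values. The share of sense calls that were higher was 61.5% on the main setting, 50% with median centring and 33.3% with the processed signals.

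Cells without alp13 gained antisense RNA over 93 genes and lost it over none, while 21 genes were higher and 9 lower on the sense strand. SPBC18H10.05 was highest at 2.31 ± 0.76, about 4.96-fold, and among further genes whose probes all moved the same way was the splicing helicase gene prp16 at 2.07 ± 0.51 over 35 probes (2168111 to 2171570 on chromosome II). The gene of the TFIIIC subunit sfc6 was at 2.0 ± 0.63 and the telomerase regulator gene est1 at 1.92 ± 0.71. Further genes were SPBPB2B2.16C at 1.92 ± 0.76, crt10 at 1.76 ± 1.04, the ribosome-biogenesis ATPase gene rix7 at 1.74 ± 0.61 and lin1 at 1.66 ± 0.63. Among the 93 genes, gpa1 was lower on the sense strand and 5 were higher (ppk31, lsd90, SPBPB2B2.16C, ftm7 and SPBPB2B2.18), and their median sense value was -0.18 against -0.14 for the other genes. The antisense median over all 811 genes was 0.12.

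In sense RNA of the alp13 mutant, genes near the right end of chromosome II again stood high, with SPBCPT2R1.02 at 2.19 ± 0.46, SPBCPT2R1.01C at 1.66 ± 0.23 and SPBCPT2R1.04C at 1.59 ± 0.33. The 3 probes of ftm7 in this region were not above background in the wild type, which makes the gene at least 2.41-fold higher. The meiotically expressed gene meu25 was at 2.12 ± 0.86, SPBC28E12.02 at 1.99 ± 0.73 and isp4, an oligopeptide transporter gene of nitrogen starvation, at 1.5 ± 0.50. The thiamine-repressed gene nmt1 was at 1.71 ± 0.32, but its wild-type signal itself differed by up to 1.68 (log2) between the arrays, at 9.36 and 9.35 on the hrp3 and double-mutant arrays of one scan session and 11.03 and 11 on the alp13 and clr3 arrays of the other. The lowest values were those of mat1-Mc at -5.67 ± 0.33, mat3-Mc at -4.70 ± 1.36 (for both, only 60% of probes were well above background in the mutant, so the size is uncertain), SPBC23G7.10C at -2.44 ± 0.41 and gpa1, the pheromone-response G protein gene, at -1.42 ± 0.45. The palmitoyltransferase gene pfa3 was at -1.34 ± 0.43 and the mitochondrial carrier gene yhm2 at -1.20 ± 0.42. The number of genes with higher antisense was 155 with the loess curve on sense probes, 195 with the processed signals and 167 with the authors' values. The share of sense calls that were higher was 70.0% on the main setting, 21.3% with median centring, 81.8% with the loess curve on sense probes and 55.8% with the authors' values.

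Cells without both hrp3 and alp13 gained antisense RNA over 96 genes and lost it over 5, and 62 genes were lower and 34 higher on the sense strand. The highest antisense value was that of rsv1, a zinc-finger transcription factor gene, at 3.06 ± 0.38, or 8.31-fold over 15 probes (2890311 to 2891770 on chromosome II). High values over genes whose probes all moved the same way were also those of prp1 at 2.81 ± 0.92, prp16 at 2.56 ± 0.84, mug93 at 2.19 ± 0.80 and dbp7 at 2.17 ± 0.82. The mitochondrial tRNA-processing gene trz2 was at 2.13 ± 0.75, the M-factor transporter gene mam1 at 2.07 ± 0.99 and SPBC12D12.05C at 2.01 ± 0.67. Of the 95 genes with higher antisense that were measured on both strands, 7 were lower on the sense strand, trz2 among them at -1.19, and 5 were higher (ppk31, lsd90, ish1, SPBC685.03 and inv1, named after their values were seen). Their median sense value was -0.24 against -0.25 for the other genes. The 5 genes with lower antisense, named after their values were seen, were SPBC336.16 at -2.24, tam10 at -1.25, pop8 at -1.07, mmp2 at -1.06 and pfd1 at -1.05. The antisense median over all 811 genes was 0.27, and the share of antisense probes well above background was 88.2% in the mutant channel against 61.7% in the wild type. The same shares were 60.2% against 46.8% on the hrp3 array, 65.5% against 55.6% on the alp13 array and 30.0% against 39.8% on the clr3 array. Between genes, the double mutant had 71.8% of probes well above background against 57.4% in the wild type. These shares were not corrected for the brightness of the channels. The median spot signals of mutant and wild type were 1794 and 148.1 on the double-mutant array and 887.7 and 274.4 on the hrp3 array. They were 460.9 and 533.5 on the alp13 array and 306.3 and 399.5 on the clr3 array.

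In sense RNA of the double mutant, lsd90 was 11.8-fold higher, at 3.56 ± 0.19, tlh2 10.2-fold, at 3.36 ± 0.43, and str1 8.69-fold, at 3.12 ± 0.43. Further genes were nmt1 at 3.31 ± 0.79 (2.29 to 3.69 over the alternatives, with the wild-type difference between scan sessions given above), SPBC19C7.04C at 3.0 ± 0.35, the invertase gene inv1 at 2.96 ± 1.05, SPBC23G7.10C at 2.89 ± 0.48 and SPBC24C6.09C at 2.71 ± 0.83. Some probes of lsd90, tlh2, str1, SPBC19C7.04C and SPBC23G7.10C (13.3% to 57.1%) were saturated in a channel, which compresses these values. Of the lowest genes, the DNA replication licensing gene cdc18 was at -2.21 ± 0.51, the Rieske protein gene rip1 at -2.14 ± 0.49 and the cytochrome c1 gene cyt1 at -1.89 ± 0.27. The kinetochore gene mis19 was at -1.79 ± 0.28, SPBC1703.13C at -1.79 ± 0.25 and mug176 at -1.72 ± 0.51. The antisense counts of this array depended strongly on the normalisation: the number of genes with higher antisense was 148 without background subtraction, 353 with median centring, 420 with the loess curve on sense probes, 319 with the processed signals, 234 with the authors' values and 153 against the mean wild type. The number of genes lower on the sense strand was 148, 36, 111 and 118 with median centring, the loess curve on sense probes, the processed signals and the authors' values, and the share of sense calls that were higher was 35.4%, against 23.7%, 65.7% and 23.9% with the first, the second and the last of these.

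**Figure D1:**
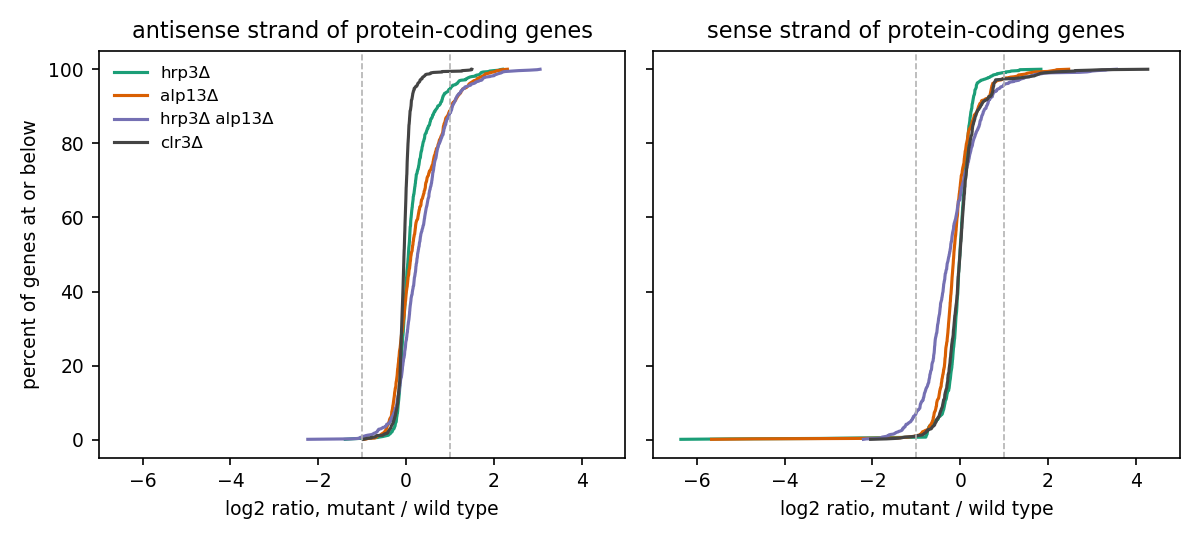
Cumulative share of genes (y axis, %) against the log2 ratio of mutant over wild type (x axis) on the antisense and the sense strand, with 1 line per mutant array. On the antisense strand the double-mutant line lies farthest to the right (median 0.27), followed by alp13 (0.12), hrp3 (0.06) and clr3 (-0.04). With median centring and with the processed signals clr3 lay above hrp3 (0.17 against -0.01, and 0.08 against -0.17).

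Antisense gains fell on many of the same genes in the 3 mutants of hrp3 and alp13. Of the 44 genes of the hrp3 array and the 93 of the alp13 array, 28 were shared, where independent lists would share 5.05. The hrp3 and double-mutant arrays shared 32 genes (5.21 for independent lists) and the alp13 and double-mutant arrays 63 (11). In all 3 mutants 26 genes had higher antisense, among them prp1, prp16, dbp7, sen34, ngl1, izh2, est1, crt10, lin1, mam1, abo2 and SPBC19C2.10. A gain in at least 1 of the 3 covered 136 genes, with 27 in the double mutant alone, such as rsv1 and mug93, and 40 in a single mutant but not in the double, such as sfr1. The clr3 array shared 0 genes with the hrp3 array, 2 with the alp13 array (ftm7 and SPBPB2B2.18) and 1 with the double-mutant array (SPBC30B4.09). Across genes, antisense values correlated at 0.69 between hrp3 and alp13, 0.63 between hrp3 and the double mutant and 0.79 between alp13 and the double mutant (Pearson; Spearman 0.70, 0.60 and 0.80). A pair of unchanged mutants that share a wild type gave 0.50 in simulation, a value fixed by the assumption of equal noise in every culture. Whether the arrays shared 1 wild-type RNA was not given in the sources used here. If they did, part of the correlation and of the overlap may come from it. The covariances were 0.16, 0.15 and 0.25, against simulated values of 0.06, 0.06 and 0.12. Correlations of clr3 with the others were 0.16, 0.11 and 0.08 on the antisense strand, all below the simulated 0.50. Its covariances with alp13 and the double mutant, 0.012 and 0.009, lay below the simulated 0.025 and 0.026. With hrp3 the covariance was 0.013, as simulated. The simulated values are therefore no firm baseline for the other pairs. On the sense strand the 6 Pearson correlations ran from 0.09 (hrp3 with clr3) to 0.49 (hrp3 with alp13), with 0.48 for alp13 and clr3. By rank (Spearman) these were 0.01, 0.19 and 0.36, so hrp3 and alp13 agreed little on the sense strand over most genes. The alp13 and clr3 arrays shared a slide and a scan session, which cannot be separated from their agreement. Genes with largely saturated sense probes, for which no direction is given below, also entered the sense correlations.

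Within genes, the antisense log2 ratios were higher over the 5' and middle parts than over the 3' part. A ratio does not give the amount of RNA gained, and antisense already present in the wild type would lower it. In the genes with higher antisense, the medians of the first, middle and last part (5' to 3', of equal length) were 1.40, 1.58 and 0.59 in the hrp3 mutant, 1.55, 1.61 and 0.57 in the alp13 mutant, and 1.52, 1.59 and 0.73 in the double mutant. The sense strand of these genes had medians at the 5' part of -0.26, -0.53 and -0.50 in the hrp3, alp13 and double mutants, and at the 3' part of 0.10, 0.08 and 0.04. Over all genes the sense medians of the 5' part were -0.06, -0.24 and -0.45, so a part of this slope was common to all genes. Higher antisense was rare in short genes: in the shortest quartile (up to 1201 bp) 2.46%, 2.46% and 2.96% of genes had it in the hrp3, alp13 and double mutants, against 5.42%, 16.7% and 18.2% in the longest. It was also rare in the quartile with the brightest wild-type sense signal, with 1 of 201 genes in the hrp3 mutant (pdi3), 0 of 201 in the alp13 mutant and 1 of 201 in the double mutant (mef1), both named after their values were seen. The genes with higher antisense had a convergent 3' neighbour in 69.1% (95% Wilson interval 59.2 to 77.6) in the double mutant, against 52.3% (48.7 to 56.0) of the other genes. In the alp13 mutant the shares were 64.1% (53.9 to 73.2) and 53.0% (49.4 to 56.6), and in the hrp3 mutant 70.5% (55.8 to 81.8) and 53.3% (49.7 to 56.8). These intervals cover counting error only.

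**Figure D2:**
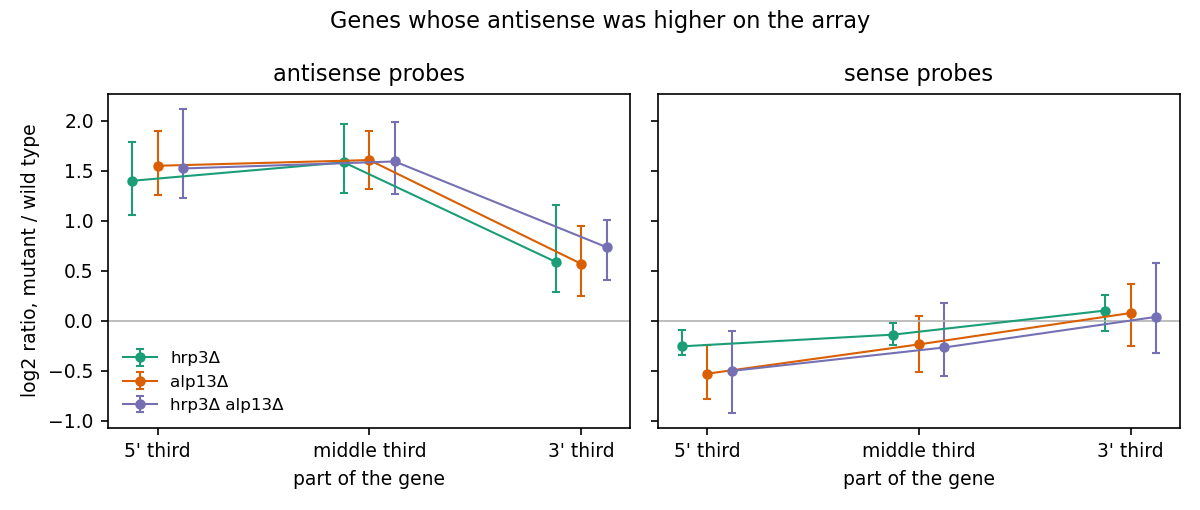
Log2 ratio of mutant over wild type (y axis) in the 5', middle and 3' parts of genes with higher antisense, for the antisense and the sense strand on the hrp3, alp13 and double-mutant arrays. Points are medians over genes and bars the quartiles, and the antisense medians of the 3' part (0.57 to 0.73) lie below those of the 5' part (1.40 to 1.55).

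The double mutant against its single mutants asks whether the 2 losses add up on the log2 scale, as the design crosses them. A sum of log2 ratios stands for fold changes that multiply. Where both single mutants gained, amounts of RNA that simply add would lie below this sum. Over 810 genes the antisense value of the double mutant lay above that of hrp3 by a median of 0.17 and above that of alp13 by 0.11. It was above hrp3 by at least 1 in 31 genes and below in 9, and above alp13 in 11 and below in 9. These counts depended on the normalisation, with 284 above and 3 below hrp3 and 162 above and 52 below alp13 with median centring, and 330 and 0, and 200 and 1, with the loess curve on sense probes. Among the 136 genes with a gain in at least 1 of the 3 mutants, the medians were 0.79 in hrp3, 1.13 in alp13 and 1.12 in the double mutant, against 1.80 for the sum of the single mutants. These genes were chosen for high values on the same arrays, which can inflate the sum, and over all 810 genes the double mutant minus the sum had a median of 0.04. In 114 of the 136 genes the double mutant was below the sum, and in 59 it was above both single mutants. Farthest above the sum was rsv1, at 3.06 against 1.37, then mug93 at 2.19 against 1.04, the securin gene cut2 at 0.97 against 0.14, nvj2 at 0.78 against -0.04 and trz2 at 2.13 against 1.37. Farthest below were the AAA ATPase gene abo2 at 1.27 against 3.37, mam1 at 2.07 against 3.87, sen34 at 1.34 against 3.06, ngl1 at 1.73 against 3.44 and SPCP20C8.02C at -0.40 against 1.27. Over all 810 genes, 9 lay above the sum by at least 1 and 58 below. That balance turned with the normalisation, to 84 above and 21 below with median centring and 105 above and 19 below with the loess curve on sense probes, and also to 138 above and 81 below with the processed signals and 125 and 87 with the authors' values. With the mean wild type it did not turn, at 33 above and 57 below. The comparison with alp13 crosses the scan sessions, and the one with hrp3 lies within 1 session.

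Cells without clr3 showed almost no antisense gains over genes, 5 higher and 0 lower, but a strong rise of transcripts in the centromeric outer repeats and at the right end of chromosome II. The 8 measured genes of the mating-type region did not share it as a set, with a sense median of -0.44. All probes of the silent copy mat3-Mc recur in mat1-Mc, which was bright in the wild type, so a rise of the silent copy alone might not show. An extra contig of the array with sequence of that region did rise in part. Where it shares sequence with the centromeric repeats, its medians were 2.66 on the plus strand and 3.32 on the minus strand. A reading frame found only on this contig (22815 to 23171, 3 probes) was at 4.66. The sense strand of tlh2 at the right end of chromosome II (4528701 to 4534660) was 19.3-fold higher, at 4.27 ± 0.87, a value that may describe its helicase family. SPBPB2B2.18 was 9.32-fold higher, at 3.22 ± 1.20. In the same end SPBCPT2R1.02 was at 2.62 ± 0.08 and SPBPB2B2.19C at 2.17 ± 0.28. Elsewhere on chromosome II the neighbours rsv1 at 2.98 ± 0.76 and rbd3, a rhomboid family gene, at 2.61 ± 0.18 were higher, with SPBC725.03 4.12-fold and SPBC19C7.04C at 1.91 ± 0.28. The antisense strand was higher for tlh2 at 1.5, ftm7 at 1.43 ± 0.18, SPBPB2B2.18 at 1.28 ± 0.97 and SPCP20C8.02C at 1.27 ± 0.44. The fifth gene, SPBC30B4.09, named after its values were seen, was at 1.5 over 2 probes and at 1.55 in the double mutant. In all, 22 genes were higher and 9 lower on the sense strand. The lowest were nmt1 at -2.04 ± 0.56, SPBC23G7.10C at -1.69 ± 0.27, the tRNA thiolation gene ctu2 at -1.49 ± 0.27, mat1-Mc at -1.37 ± 0.19, cdh1 at -1.32 ± 0.16 and mat3-Mc at -1.26 ± 0.21. The wild-type signal of nmt1 on this array was 11 (log2), against 9.35 on the double-mutant array. With Agilent's processed signals 50 genes were higher, and with median centring 27 were lower, which took the share of higher calls from 71.0% to 43.8%.

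The outer repeats of the chromosome II centromere, the sites of pericentromeric heterochromatin, gave more RNA from both strands without clr3. In the left repeats (1603318 to 1620092) the median was 1.87 on the plus strand and 2.66 on the minus strand, with 69.9% and 75.5% of probes at or above 1. In the right repeats (1631923 to 1645648) the medians were 2.51 and 1.75, with 76.6% and 65.7% of probes. The central domain between them (1620093 to 1631922) stayed at 0.04 and 0.02, and the tRNA clusters on the left flank at 0.01 and 0.11. In the hrp3, alp13 and double mutants the medians of the outer repeats lay between -0.07 and 0.08. The shares of probes at or above 1 there, left plus, left minus, right plus and right minus, were 0% throughout in hrp3, 1.95%, 8.92%, 10.9% and 3.68% in alp13, and 3.85%, 10.8%, 8.76% and 3.68% in the double mutant. Most probes of the outer repeats recur on the array, so the values describe the repeat family, and the probes that occur once had clr3 medians of 0.32 and 2.90 on the left and 0.95 and 0.07 on the right.

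**Figure D3:**
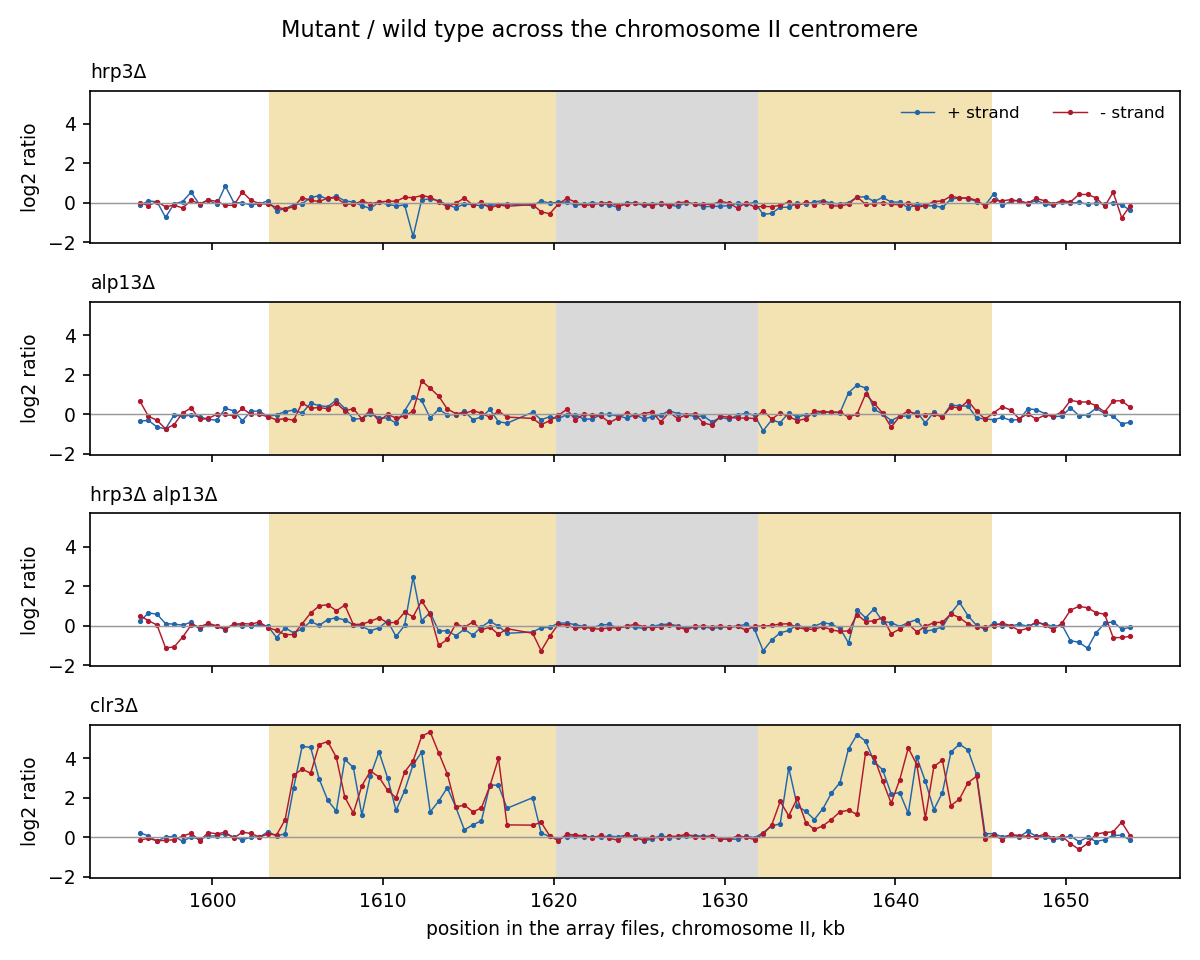
Median log2 ratio of mutant over wild type (y axis) in bins of 500 bp across the chromosome II centromere (x axis, array-file position), per strand and mutant, with outer repeats and central domain shaded. The clr3 line rises over the outer repeats (medians of 1.75 to 2.66) and stays near 0 over the central domain.

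At the right end of chromosome II, the 11 measured genes had a median sense value of 0.85 in the hrp3 mutant, 1.48 in the alp13 mutant, 0.23 in the double mutant and 1.76 in the clr3 mutant. Of these genes, 5 were higher and 1 lower in the hrp3 mutant, 9 were higher in the alp13 mutant and 9 in the clr3 mutant. The median lay above those of all 10000 random lists in these 3 mutants and at percentile 95 in the double mutant, where tlh2 alone was higher. SPBPB2B2.16C was at 2.20 in the alp13, 1.70 in the clr3 and 0.02 in the double mutant. SPBPB2B2.18 was at 2.47 in the alp13 mutant and 0.65 in the double. The telomere-linked helicase gene tlh2 differed between all mutants, at -3.19, 1.13, 3.36 and 4.27 in hrp3, alp13, double and clr3. With other normalisations the median of the double mutant ran up to 0.99. The antisense medians of the list were 0.02, 0.12, 0.03 and 0.19 in hrp3, alp13, double and clr3, with 3 genes higher in alp13 (SPBPB2B2.16C, SPBPB2B2.18 and ftm7) and 3 in clr3. Over the alternatives these medians ran from -0.30 to 0.06, -0.28 to 0.34, -0.39 to 0.10 and 0.08 to 0.73.

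**Figure D4:**
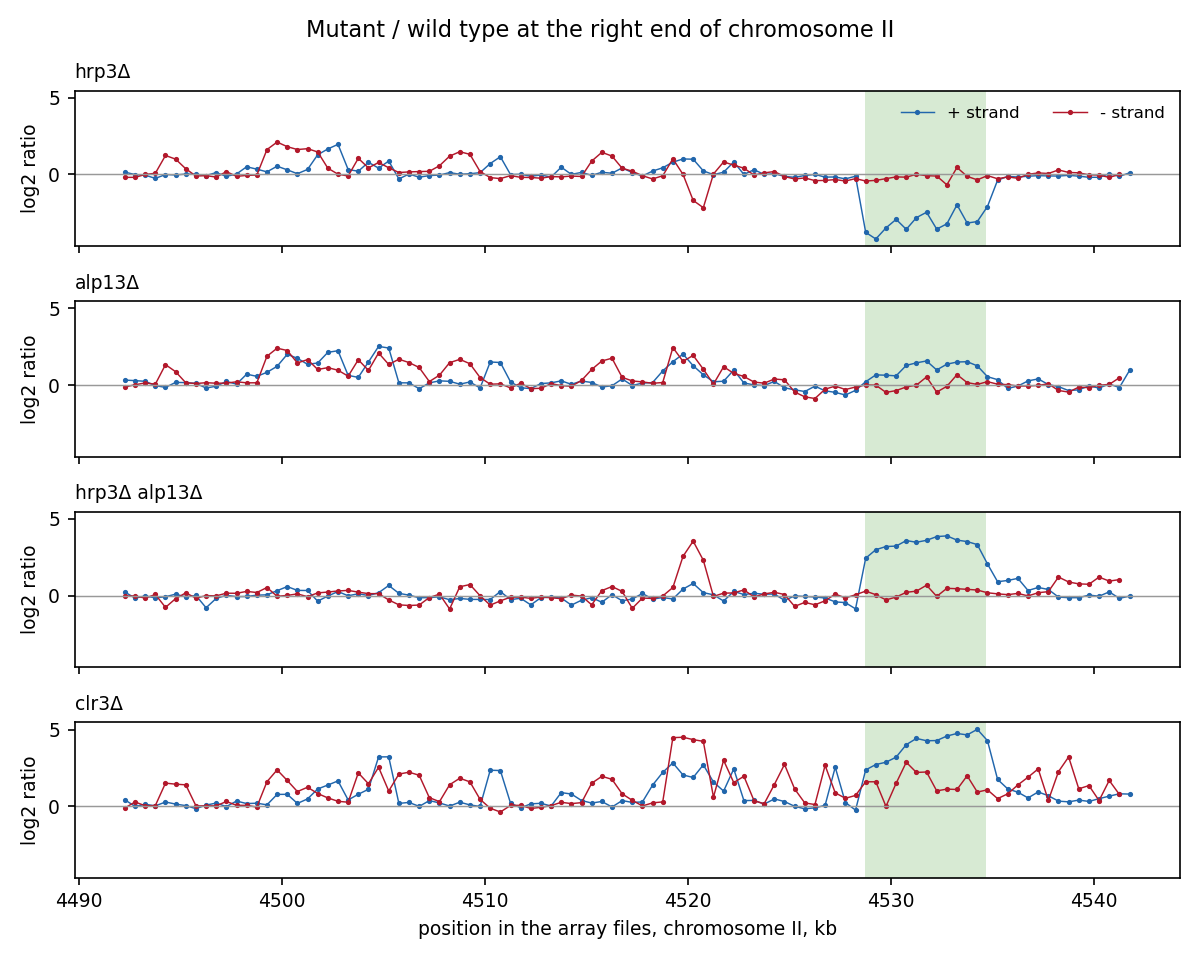
Median log2 ratio of mutant over wild type (y axis) in bins of 500 bp along the tiled right end of chromosome II (x axis, array-file position), per strand and mutant, with tlh2 shaded. Over tlh2 the hrp3 line falls (gene value -3.19) while the clr3 line rises (4.27).

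In the mating-type region, 3 of 8 measured genes were lower on the sense strand in each of the hrp3, alp13 and clr3 mutants (mat1-Mc, mat3-Mc and SPBC23G7.10C), and 3 were higher in the double mutant. Since all probes of mat1-Mc and mat3-Mc recur between the cassettes, these genes may stand for a single signal. Without recurring probes the lower sense genes of the hrp3 mutant numbered 3 in place of 5. The list medians were -0.67, -0.27, 0.74 and -0.44 for hrp3, alp13, double and clr3, at percentiles of 0.0, 16, 99.9 and 0.01 of random lists. Over the alternatives these medians ran from -1.27 to -0.44, -0.60 to -0.07, 0.25 to 0.74 and -1.39 to -0.31. In the double mutant SPBC23G7.10C was at 2.89, mag2, a DNA glycosylase gene, at 1.21 and SPBC23G7.13C at 1.1, while mat1-Mc stood at 0.06 and mat3-Mc at 0.17. The antisense medians of the region were -0.35, -0.45, 0.09 and -0.13 in hrp3, alp13, double and clr3, at percentiles of 0.0, 0.0, 53.8 and 3.59.

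Among pheromone and mating genes, 2 of 5 had higher antisense in the hrp3, alp13 and double mutants: gpa1 at 1.14, 2.02 and 2.40, and mam1 at 1.70, 2.17 and 2.07. The antisense values of the pheromone-signalling kinase gene byr2 were 0.10, 0.88 and 0.79 and those of rep1 -0.01, 0.86 and 0.63. Among meiotic genes, the recombination gene rec14 had antisense values of 1.36, 2.17 and 2.20 and spo5 of 0.79, 1.76 and 1.74, while rec6 was at -0.04, 0.09 and -0.95 and the meiotic cohesin gene rec8 at -0.09, 0.73 and 0.61. The rec14 value in hrp3 ran from 0.68 to 1.94 over the alternatives. On the sense strand gpa1 was lower in the alp13 mutant and rec8 lower in the double mutant, at -1.17. That rec8 value moved to -0.02 under another normalisation. The list percentiles on the antisense strand were 17.2, 87.4, 83.9 and 42.0 for mating and 10.9, 61.2, 44.4 and 15.8 for meiosis in hrp3, alp13, double and clr3. On the sense strand they were 13.6, 68.7, 44.4 and 91.7 for mating and 45.8, 59.5, 54.1 and 26.3 for meiosis.

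Ribosome-biogenesis genes had low sense values in the double and clr3 mutants, with list medians of -0.79 and -0.50 over 9 genes, at percentiles of 0.13 and 0.01. In the double mutant rrs1 was lower at -1.07, with rrb1 at -0.96 and utp18 at -0.91, and in the clr3 mutant rrb1 was lower at -1.0, with nog1 at -0.93. The medians of hrp3 and alp13 were -0.01 and -0.21, at percentiles of 26.6 and 19.5. On the antisense strand utp18 was higher in the alp13 mutant at 1.05 and in the double mutant at 1.24, and mak5 in the double mutant at 1.04, and the list percentiles were 86.2, 55.5, 38.6 and 32.9. Antisense values of 23 ribosomal protein genes were low in the hrp3 and alp13 mutants, with medians of -0.16 and -0.33 that lay below all random lists. The double mutant had -0.13, at percentile 0.70, and clr3 -0.07, at 7.50, which turned to 0.19 with median centring. The random lists were matched on antisense signal, not on sense signal or gene length. All genes of the brightest sense quartile had antisense medians of -0.07 in hrp3 and -0.17 in alp13. Over the alternatives the ribosomal protein medians ran from -0.82 to -0.08 in hrp3, -0.90 to -0.03 in alp13 and -1.65 to -0.13 in the double mutant. The lowest single values were those of rps1002 at -0.69, rpl1102 at -0.56, rpl802 at -0.55 and rps1601 at -0.52, all in the alp13 mutant. The sense probes of ribosomal protein and glycolysis genes, such as rpl1701, rpl4302, rps3002, rps2501, tdh1 and pfk1, were largely saturated, so no direction is given for them. The antisense values of tdh1 were -0.07, -0.28, -0.05 and 0.01 and those of pfk1 -0.22, -0.33, -0.20 and -0.13.

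Among stress-induced genes, hsp3101 was at 0.98 in the double and higher at 1.61 in the clr3 mutant on the sense strand, and the nuclear-envelope stress gene ish1 was higher at 1.79 and 1.81. On the antisense strand hsp3101 and ish1 were higher at 1.61 and 1.28 in the alp13 mutant and at 1.94 and 1.33 in the double. The sense strand of hsp16 was at 2.07 in the double, with 87.5% of its probes saturated in a channel, and -0.78 in the clr3 mutant, and the sense values of the glutathione peroxidase gene gpx1 were 0.18, -0.11, 0.77 and 0.65 in hrp3, alp13, double and clr3, with 85.7% of probes saturated in the double. Among chaperones the disaggregase gene hsp78 was higher at 1.28 in the alp13 and 1.61 in the double mutant, with 0.91 in hrp3 and -0.87 in clr3, while aha1 had 0.63, 0.79, 0.85 and 0.15. Over the alternatives hsp78 fell under the threshold in both, down to 0.81 in alp13 and 0.91 in the double mutant. In the double mutant 41.7% of the probes of hsp78 and 41.2% of those of aha1 were saturated, and mas5 had up to 72.2% saturated, so no direction is given for it. The starvation genes inv1 and isp4 were higher in the alp13 mutant, at 1.33 and 1.5, and in the double, at 2.96 and 1.46, and inv1 also in clr3 at 2.42. The antisense strand of inv1 was higher in the double mutant at 1.02, and fnx1 had sense values of -0.34, -0.20, -0.27 and -0.20. In iron uptake, str1 was lower at -1.63 in hrp3 and -1.13 in alp13 and higher at 3.12 in the double, and the regulator gene php4 had sense values of -0.36, -0.81, 0.59 and -0.20 with higher antisense in alp13 at 1.47. The phosphate regulator gene pho7 had higher antisense in alp13 at 1.05 and sense values of -0.22, -0.61, 0.35 and 0.03. The hexose and glucose-repressed list had inv1 as its 1 measured member.

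On the short lists of heterochromatin, remodeller and histone-chaperone genes, the SHREC subunit gene clr1 was higher on the antisense strand in the alp13 and double mutants at 1.28 and 1.25, the remodeller gene hrp1, a relative of hrp3, at 1.29 and 1.25, and the histone chaperone gene slm9 at 1.26 and 1.1. Over all genes 11.5% and 11.8% were higher there, and these lists are too short for a comparison with random lists. In the hrp3 mutant these genes were at 0.82, 0.82 and 0.84, and in clr3 at 0.17, -0.11 and -0.02. The RNA-silencing gene tas3 was at 0.98 in both the alp13 and the double mutant, and the Clr6-complex genes pst3, pst1 and png2 at 0.61, 0.64 and 0.19 in the double. On the sense strand clr1, hrp1, slm9, tas3, pst1, pst3 and png2 all lay between -0.37 and 0.39 on every array. The histone genes hht2 and hhf2 were partly saturated on the sense strand, with up to 83.3% and 75% of probes, so no direction is given for them there, and hht2, hhf2 and pht1 had antisense values from -0.32 to 0.09. Of the 2 measured MBF-regulated genes, cdc18 was lower in the double mutant at -2.21 and yox1 was at -0.68 there, with antisense values of 0.33 and 0.99. For the Tf2 retrotransposons Tf2-9 and Tf2-10, 89.7% and 89.5% of sense probes were saturated in a channel in the double mutant, so no direction is given there. Their sense values were 0.68 and 0.57 in hrp3, 0.81 in alp13 for both, and 0.07 and 0.11 in clr3, with 17.9% to 35.9% of probes saturated, and describe the family because the probes recur. The strain marker leu1 had up to 76.9% of its sense probes saturated, so no direction is given for it. No member of the deleted-gene, wtf, mitosis and septation, flocculation or RNA decay lists was measured.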

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

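The filter on probes above background in both channels, the removal of recurring probes and the means over probes for named genes were chosen after the data were seen, and all other alternatives before. The results that moved are given by setting, and the cause was not tested. Named genes were followed under 7 alternatives: no background subtraction, median centring, the loess curve on sense probes, the processed signals, the authors' values, the mean wild type and means over probes. No named gene past the threshold changed sign under these: of 991 comparisons, 883 stayed within the spread over probes and 108 moved further. Of the counts of genes with higher antisense, 30 stayed within 1.5 times the main count and 14 did not. For sense these were 41 and 3 for higher genes and 33 and 11 for lower genes, and 53 of 264 list medians and 17 of 72 correlations moved. Of 142 named values past the threshold, 22 fell under it in at least 1 alternative, among them hsp16 sense in hrp3 (down to 0.98), prp1 antisense in hrp3 (0.86), tlh2 sense in alp13 (0.68), yhm2 sense in alp13 (-0.96) and rec8 sense in the double mutant (-0.02).

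Without background subtraction the double mutant had 148 genes with higher antisense, with 64 above hrp3 and 19 above alp13 by at least 1.

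With median centring in place of loess, the double mutant had 353 genes with higher antisense. Lower sense genes numbered 10 in hrp3, 59 in alp13, 148 in the double mutant and 27 in clr3. The antisense difference of double and hrp3 had a median of 0.67, with 284 genes above and 3 below, and that of double and alp13 had 162 above and 52 below. Against the sum, 84 genes were above and 21 below. Antisense correlations were -0.11 (hrp3 and clr3), 0.22 (alp13 and clr3) and -0.0672 (double and clr3). Sense correlations were 0.34 (hrp3 and alp13), 0.29 (hrp3 and double) and 0.60 (alp13 and clr3). Sense list medians were 0.0422 (mating, hrp3), -0.0814 (mating, clr3), 0.55 (meiosis, double), -0.70 and -0.88 (ribosome biogenesis, alp13 and clr3), 0.67 (right end, double) and 0.25 (mating-type region, double). Antisense list medians were -0.86 and 0.19 (ribosomal proteins, double and clr3), 0.90 (ribosome biogenesis, double), and -0.24 and -0.39 (right end, hrp3 and double).

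With the loess curve on sense probes, higher antisense was seen in 67 genes of hrp3, 155 of alp13 and 420 of the double mutant. The double mutant had 69 higher and 36 lower sense genes. The antisense difference of double and hrp3 had a median of 0.82, with 330 genes above and 0 below, and that of double and alp13 a median of 0.63, with 200 above and 1 below. Against the sum, 105 genes were above and 19 below. Sense correlations were 0.62 (hrp3 and alp13), 0.19 (hrp3 and clr3) and 0.45 (alp13 and double). Sense list medians were 0.0644 and 0.45 (mating, hrp3 and double), 0.68 (meiosis, double) and 0.99 (right end, double), and antisense list medians 1.60 (meiosis, double) and 1.21 (ribosome biogenesis, double).

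With Agilent's processed signals, higher antisense was seen in 98 genes of hrp3, 195 of alp13 and 319 of the double mutant. Higher sense genes numbered 41 in alp13 and 50 in clr3, and lower sense genes 22 in hrp3, 14 in alp13 and 111 in the double mutant. The double mutant was above hrp3 in 246 genes and below in 24, above alp13 in 92 and below in 22, and above the sum in 138. The antisense correlation of hrp3 and clr3 was -0.0604. Antisense list medians were 1.86 (mating, double), -0.49, -0.73 and -0.68 (ribosomal proteins, hrp3, alp13 and double), 1.07 (ribosome biogenesis, double), -0.30 and 0.57 (right end, hrp3 and clr3), and -0.83 and -0.43 (mating-type region, alp13 and clr3). Sense list medians were -0.26 (mating, hrp3), -0.22 (meiosis, hrp3), 1.16 and 2.12 (right end, hrp3 and clr3), and -1.27 and -1.19 (mating-type region, hrp3 and clr3).

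With the authors' values, higher antisense was seen in 84 genes of hrp3, 167 of alp13, 234 of the double mutant and 8 of clr3. Lower sense genes numbered 19 in alp13 and 118 in the double mutant. The double mutant was above hrp3 in 194 genes and below in 43, above alp13 in 79 and below in 27, and above the sum in 125. The sense correlation of alp13 and double was 0.42. Antisense list medians were 1.79 and 1.77 (mating, alp13 and double), -0.45 (meiosis, clr3), -0.82, -0.90 and -1.65 (ribosomal proteins, hrp3, alp13 and double), -0.50 (ribosome biogenesis, alp13), -0.24, -0.28 and 0.73 (right end, hrp3, alp13 and clr3), and -0.66, -0.89 and -0.83 (mating-type region, hrp3, alp13 and clr3). Sense list medians were -0.22 (meiosis, hrp3), 1.13 (right end, hrp3) and -1.39 (mating-type region, clr3).

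Against the mean of the 4 wild-type channels, the double mutant had 153 genes with higher antisense, with 98 above hrp3, 30 above alp13 and 33 above the sum. Antisense correlations were 0.56 (hrp3 and alp13), 0.47 (hrp3 and double), -0.12 (hrp3 and clr3), -0.25 (alp13 and clr3) and -0.31 (double and clr3), and the sense correlation of hrp3 and clr3 was 0.23. List medians were -0.45 (mating, antisense, clr3), 0.14 (mating, sense, hrp3), -0.47 (ribosomal proteins, antisense, double) and 0.73 (ribosome biogenesis, antisense, double).

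Without recurring probes, 3 genes were lower on the sense strand in hrp3. With the filter on both channels, 3 genes had higher antisense in clr3. With means over probes, 7 genes were above alp13 in the double mutant.

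Relative to the main setting, the antisense median of all genes in the double mutant moved by 0.52 with median centring, 0.80 with the loess curve on sense probes and 0.39 with the processed signals, and the sense median by -0.15, 0.16 and -0.10. In alp13 the antisense median moved by 0.22 and 0.14 under the first and second of these and the sense median by -0.42 and 0.13. In hrp3 the antisense median moved by -0.23 with the processed signals and -0.27 with the authors' values. In clr3 the antisense median moved by 0.21 with median centring, 0.12 with the processed signals and -0.22 with the authors' values, and the sense median by -0.33 with median centring and -0.13 with the authors' values. Rank correlations of antisense values with the main setting were 0.93 to 0.99 in alp13, 0.89 to 0.995 in the double mutant, 0.76 to 0.99 in hrp3 and 0.52 to 0.89 in clr3, where much of the gene order changed. Signal over background limits the antisense values, since 30.0% to 61.7% of antisense probes on the clr3 mutant channel and the wild-type channels were well above background. No paired analysis was possible because each genotype had 1 array, and slide could not be fitted as a block for that reason.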

Other observations

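The tests on mat1-Mc and tlh2 were chosen only after their values were seen, and those on higher antisense before. The genes rsv1 and rbd3, which lie side by side on chromosome II (2890261 to 2893620), behaved differently in the mutants. In clr3 cells both sense strands were higher, at 2.98 and 2.61, and rsv1 antisense was at -0.53. In the double mutant rsv1 was higher on the antisense strand (3.06) with 0.68 on the sense strand, and rbd3 was higher on the sense strand (1.90) with 0.03 on the antisense strand. The gene lsd90 was higher on the sense strand in 3 mutants, at 1.32 in alp13, 3.56 in the double and 1.84 in clr3, and on the antisense strand in alp13 at 1.07 and in the double at 1.23. The kinase gene ppk31, chosen after its values were seen, was higher on both strands in alp13 (1.23 sense, 1.63 antisense) and in the double mutant (1.70 and 1.75). The galactokinase gene gal1, chosen in the same way, was higher on the sense strand in alp13 at 1.02 and in clr3 at 1.69, with -0.10 in the double mutant.

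Beyond the rRNA genes at the left end of chromosome III (23131 to 49970), 12% of plus-strand and 10.2% of minus-strand probes were at or above 1 in clr3 cells, with medians of 0.23 and 0.31. The shares were 12.7% and 9.70% in alp13, 10% and 10.8% in the double mutant, and 1.5% and 9.06% in hrp3. The extra contig of the array, which holds sequence of the mating-type region, shares sequence with the centromeric outer repeats (contig positions 28657 to 32813). Its medians in clr3 were 2.66 on the plus strand and 3.32 on the minus strand, with 90.2% and 80.5% of probes at or above 1, and the probes that occur once had 2.23 and 2.92. The 3 other mutants had medians from -0.07 to 0.25 there, with plus-strand and minus-strand shares at or above 1 of 0% and 0% in hrp3, 2.44% and 26.8% in alp13, and 12.2% on each strand in the double mutant.

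Higher antisense in the hrp3, alp13 and double mutants was weighed against 3 explanations. Copying of raised sense RNA during labelling would raise both strands together. The highest ratio of median sense to median antisense over these arrays was -0.0559, below the 0.25 set in advance. A copying rate that differed between mutant and wild-type labelling would leave the sense ratios as they are, so this test does not cover it. Such copying would show most in genes with a bright sense signal. In the brightest quartile 1, 0 and 1 of 201 genes had higher antisense in the hrp3, alp13 and double mutants, which argues against it. A dye bias of the probes common to all arrays would recur on every array. On the clr3 array the genes with higher antisense had a median of at most -0.0212 times their own, which argues against such a common bias. A bias tied to the scan session or to the brightness of the channels need not recur on the clr3 array. The hrp3 and double-mutant arrays came from the other session and both had higher antisense, so such a bias stays open for them. Transcription that reads in from a convergent neighbour stays open and may contribute, since a convergent 3' neighbour was more frequent by up to 17.2 percentage points while the 3' part had the lowest median. A share of this RNA may be antisense that the wild type already has at the 3' end, and the arrays cannot separate it, so this explanation and a start of transcription inside the gene cannot be told apart.

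The fall of mat1-Mc in the hrp3 and alp13 mutants was absent in the double mutant. The wild-type signal of mat1-Mc varied by 0.588 (log2) over the arrays, too little for falls of -6.36 and -5.67. Whether each deletion brings a fall on its own that adds up stays open, since the value of the double mutant, 0.0611, is itself part of the pattern and comes from 1 strain on 1 array. A candidate explanation is another mating type in both single-mutant strains, since an open reading frame found only on the extra contig (22815 to 23171, 3 probes) was at 2.65 in alp13. In hrp3 all 3 of its probes were well above background against 1 in the wild type, and in the double mutant 1 of 3 was in either channel, which leaves no usable ratio there. The same frame was at 4.66 in clr3, where mat1-Mc was at -1.37, the mating types were not given in the sources used here, and a loss of silencing in a mixed culture was not tested.

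The sense strand of tlh2 was at -3.19 in hrp3 and higher in the other mutants. Its wild-type signal varied by 0.480 (log2) over the arrays, below the smallest of the 4 values in size, 1.13. A few faulty probes were excluded, as 98.2% of its probes that occur once on the array were below 0 in hrp3. Fewer copies of the sequence in the hrp3 strain would lower both strands. The other strand was at -0.264, but its wild-type signal of 7.645 (log2) lay so close to the lowest signal above background in the mutant channel, 7.088, that such a fall could not show, and this explanation stays open. A change of transcription in this strain, inherited or brought by the deletion, is open as well, and 1 culture cannot separate these.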
